A study of Homo sapiens with 23 samples.

How the data were processed

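Exons trapped from randomly fragmented HEK293 genomic DNA were measured in 23 samples, which the labels place in 5 assays. Per the labels' protocols, reporter plasmids were transfected transiently, polyadenylated RNA was selected, and RT-PCR with 2 rounds of PCR amplified the sequence between constant parts of the reporter transcript. Per the submitters' processing notes, HISAT2 2.2.1 and the hg38 build were used. The counting tool, the filter that set the lowest value and the handling of reads with several map positions are not given in the sources used here. The deposited table gives counts: per the file headers, each exon has a count, which equals in every row the sum of that row's library counts, in whole reads with no normalization. The lowest count was 100, so the authors' table holds only exons with at least 100 reads in total. A deposited list of exon positions held the same exons in the same order and added no values.

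Each row of the table joins 24 library values without names. The first was 0 for every exon and 23 had reads. Because no name ties a value to a sample, none of the 24 positions was matched to a sample, assay or replicate, and neither their order nor their values were used to do so. The libraries served only as an unordered set: for the range and median of their totals, the number of libraries with a read of an exon, the share of its reads in its top library, random draws of libraries, runs that left out 1 library each, and a grouping of libraries by shared exons. Tests planned before the data were examined therefore could not be made for differences between assays, for each assay against the others, or for values per assay. The planned comparisons of annotated internal exons (protein-coding against long noncoding, constitutive against alternative, length classes as a share of annotated exons), of sense against antisense introns, and of GC content and splice-site scores need exon positions, gene strands or a genome, which were not used here. PCR reads carry no molecular identifiers, so read counts are not independent molecules.

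In place of annotated exons, exons were placed by their midpoint in gene spans of the RefSeq gene table of GRCh38 patch 14, whose chromosomes share coordinates with hg38. The table gave 59792 genes, of which 58998 had a place on a primary chromosome. Where spans overlapped, protein-coding genes took precedence over lncRNA genes, then pseudogenes, then other genes. The sources do not state how starts are counted. They were taken to count from 0, as is usual for the format of the deposited list of positions, and because lengths divisible by 3 were in excess under that reading, which was seen before the comparison of such lengths was chosen. Exon length is therefore end minus start, and printed positions add 1 to the start. If starts count from 1, lengths are 1 nt longer and printed starts 1 nt too high. Chromosome 11 had 7175 exons, all with a read in the same library, against 73171 on chromosome 10 and 69894 on chromosome 12. It was therefore left out of all comparisons, as were chromosome Y and mitochondrial DNA. Density was the number of exons per Mb of sequence in windows of 100 kb that held at least 1 trapped exon.

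Each comparison of classes was computed per chromosome, and the 22 values were tested against 0 with a two-sided sign-flip permutation test of 100000 resamples, whose smallest p is 1e-05. Chromosomes stand in for replicates, so these p-values measure the spread between chromosomes, not between cultures. Benjamini-Hochberg adjustment covered the 9 comparisons. The density of genes against sequence outside genes, read level and exon length were adapted from the plan, with gene spans in place of annotated exons. The other 5 comparisons of class (libraries per exon, both comparisons of lengths divisible by 3, exons of at least 10 libraries against exons of 1 library, and shared splice sites), the correlation over chromosomes, the contrast of protein-coding with lncRNA spans by density and the limit of 10 libraries were chosen after the data were seen. Shares have 95% Wilson intervals, which cover counting error only.

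Gene values counted exons that lie within the gene span on either strand. The precedence of classes was not used there, so an exon in overlapping spans counted for each gene. For each of the 12 gene lists fixed beforehand, the median of log2 of exons plus 0.5 per 10 kb was set against 10000 random lists, each drawing at random for every member, with repeats allowed, 1 of the 100 protein-coding genes (lncRNA genes for the noncoding list) nearest in length. The p-value is two-sided, with a smallest value of 0.0002, and was adjusted over the 12 lists. Each member was drawn for independently, so list members that are neighbours on a chromosome were treated as independent genes. Only the lists were fixed beforehand: this test replaced the planned Fisher exact test of annotated internal exons trapped and not trapped. Genes of chromosome 11 dropped out, and older symbols were matched through synonyms. The rule for named genes was adapted because annotated exons and assays were not used. It names from each list the 2 densest and 2 sparsest genes with at least 5 exons, by density not matched on gene length. It names as well the 10 protein-coding and 5 intergenic exons with the most reads among exons seen in all 23 libraries. It also names the 5 protein-coding genes with the most exons on their fuller and on their emptier strand, and the 5 densest and 5 sparsest with at least 20 exons. The part on differences between assays named none, and some genes that the rule names from the lists are not given here.

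Code was tested on simulated data. A planted 1.5-fold density in genes came back as 1.49-fold, and a planted excess of 5 percentage points in lengths divisible by 3 came back as 4.68 points. Of 180 tests on 20 simulated tables without differences, 3.89% had p under 0.05. For gene lists, 5.5% of 200 random lists of 20 genes had p under 0.05, and 87.5% of lists with a planted 2-fold density were found. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

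Alternatives fixed before the data were examined and run here were autosomes only and protein-coding genes only as genes. Added after the data were seen were exons of at least 1000 reads, exons in at least 5 libraries, 1 exon per group of overlapping exons, the sequence from the first to the last exon as searched sequence, both exon ends in the class, each library left out in turn, and for the lists exons in at least 10 libraries and matching on length and on exon density in the 1 Mb around the gene, 0.5 Mb on each side. A first form of this matching gave genes longer than 1 Mb no flanking sequence, and it was corrected after its results had been seen. The core spliceosome and muscle lists kept their calls in the first form and lost them after the correction.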

Results

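Exon trapping asks which stretches of genomic DNA carry enough information to be spliced as an exon when they are taken out of their gene. HEK293, an established line of human embryonic kidney cells, supplied both the DNA and the cells. Its genomic DNA was broken at random, cloned between the splice sites of a reporter plasmid and transfected, and exons that the cells spliced into the reporter transcript were recovered from RNA by RT-PCR and sequenced. The labels describe 23 samples in 5 assays of the same kind, 3 assays with 5 samples and 2 assays with 4 samples each. The deposited table lists 1470874 trapped exons, each with its position, its strand, its reads summed over all libraries and the reads of each library. No library in the table carries the name of an assay or a replicate, so assays were not compared here and the 23 libraries with reads entered only as an unordered set. Positions refer to the hg38 build.

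The table held 4108785553 reads, and the libraries ranged from 128824336 to 251620599 reads around a median of 170211116. A single library recovered between 168448 and 409946 of the exons, with a median of 247552. Exons had a median of 574 reads, with quartiles of 216 and 2117 reads, and the strongest had 506250 reads. None had fewer than 100 reads. Trapped exons were short: their median length was 139 nt, 5% were under 63 nt and 5% were over 351 nt. They lay on both strands in nearly equal numbers, with 49.8% on the plus strand.

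Most exons were seen in few libraries. The median exon had reads in 3 of the 23 libraries, 18.2% of all exons were seen in 1 library, 91674 exons (6.23%) were seen in at least 10 libraries, and 191 were seen in all 23. For these counts 1 read was enough for an exon to be seen in a library. With at least 10 reads required, 33.8% of exons were seen in 1 library only. A typical exon drew a median of 79.9% of its reads from its top library. Drawing libraries at random from the set, 10 libraries recovered an expected 1173541 exons of the table and 22 libraries recovered 1459252, so the last library added 11622 exons. This count covers only exons that passed the minimum of 100 reads over all libraries.

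The first question was whether random genomic fragments yielded trapped exons more often inside genes than outside them. Chromosome 11 was left out because its 7175 exons all came from the same library. Exons placed on mitochondrial DNA or chromosome Y were set aside, which left 1463508 exons on 22 chromosomes. Protein-coding gene spans held 768361 of these exons (52.5%) and 64.4% of the reads, lncRNA gene spans held 174011 (11.9%), and sequence outside annotated genes held 495539 (33.9%). Density was 690 ± 224 exons per Mb in protein-coding spans, 554 ± 155 in lncRNA spans and 456.3 ± 93.8 outside genes (mean ± SD, n = 22 chromosomes). Pseudogene spans, at 656 ± 161, were close to protein-coding spans. Genes of all kinds held 1.42 times as many exons per Mb as sequence outside genes, a log2 ratio of 0.50 ± 0.19 (SD, n = 22), and the ratio was above 1 on 22 of 22 chromosomes (two-sided sign-flip permutation test, p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 1.29e-05 over 9 comparisons). For genes of all kinds, chromosome 19 had the widest gap (log2 ratio 0.98). Its protein-coding spans alone held 1224 exons per Mb, against 593 outside genes. Chromosome 10 had the narrowest gap (log2 ratio 0.27), with 592 in protein-coding spans alone and 491 outside genes. Lengths were not corrected for bases where reads cannot be placed uniquely, and gene spans include annotated exons. The cause of the gap was not tested.

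Protein-coding spans were denser than lncRNA spans by 0.30 ± 0.20 on the log2 scale (SD, n = 22), or 1.23-fold, and 20 of 22 chromosomes showed this direction (permutation p = 2e-05, adjusted p = 2e-05). The exceptions were chromosome 13, with 392 exons per Mb in protein-coding and 399 in lncRNA spans, and chromosome 10, with 592.1 and 593.0. These densities count whole gene spans, introns included. Requiring a read in at least 5 libraries widened this log2 ratio to 0.59, and counting 1 exon per group of overlapping exons narrowed it to 0.19, both alternatives chosen after the data were seen.

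**Figure D1:**
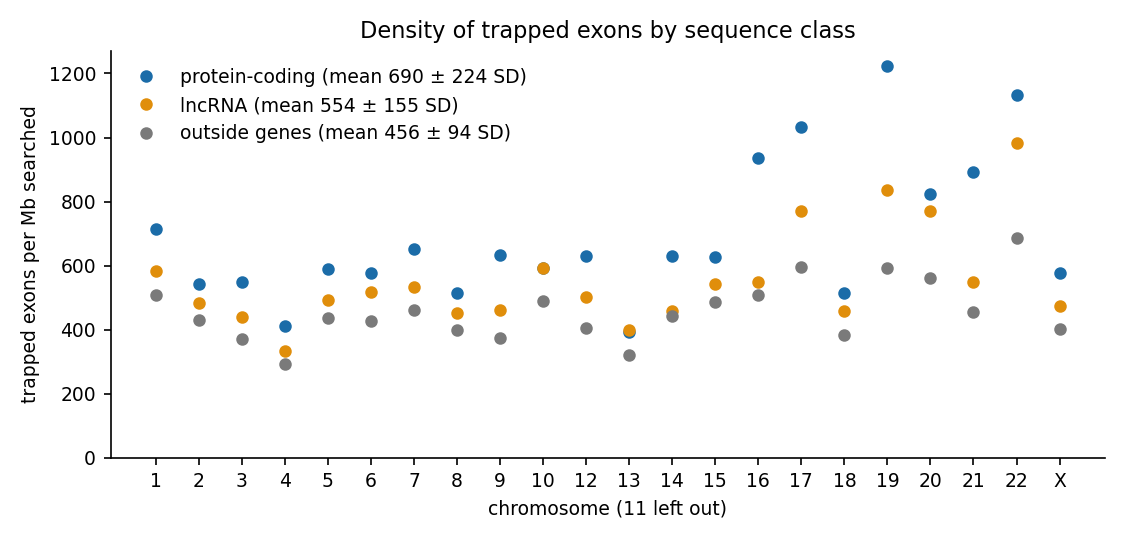
Trapped exons per Mb of searched sequence (vertical axis) on each of the 22 analysed chromosomes (horizontal axis), with 1 point per chromosome for protein-coding spans, lncRNA spans and sequence outside genes. Protein-coding points lie above the points for sequence outside genes on every chromosome, and the legend gives the mean and SD over 22 chromosomes.

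Gene-rich chromosomes yielded more trapped exons. Chromosome 19, with 25.2 protein-coding genes per Mb, gave 973 exons per Mb, whereas chromosome 4, with 4.05 genes per Mb, gave 345. Across the 22 chromosomes, exon density correlated with the density of protein-coding genes (Pearson r = 0.87, permutation p = 1e-05; Spearman rho = 0.91, permutation p = 1e-05; adjusted p = 2e-05 for both over 2 relations). Without chromosomes 19 and 17, which lay farthest from the median gene density, r was 0.91 and rho 0.88. Exons outside genes followed the same relation, with r = 0.72 (permutation p = 0.0003, adjusted p = 0.0003) and rho = 0.81 (permutation p = 3e-05, adjusted p = 3e-05), and without those chromosomes r was 0.84 and rho 0.75.

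Exons in protein-coding spans were also read more and seen more often than exons outside genes. Median reads were 628.1 ± 40.1 in protein-coding spans and 510.5 ± 9.0 outside genes (mean ± SD of chromosome medians, n = 22), a log2 difference of 0.30 ± 0.08. They were found in 4.38 ± 0.55 libraries on average against 3.82 ± 0.43 outside genes, a difference of 0.55 ± 0.18 libraries. Both differences held on 22 of 22 chromosomes (permutation p = 1e-05, adjusted p = 1.29e-05 for each). Exons in pseudogene spans were found in 4.28 ± 0.50 libraries on average, close to the protein-coding value. With only exons found in at least 5 libraries, an alternative added later, the log2 difference in reads was 0.56, and with only exons of at least 1000 reads the difference in libraries was 0.84.

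Exons seen in many libraries lay mostly in protein-coding spans. Exons found in at least 10 libraries made up 8.04% of those in protein-coding spans, 4.14% of those in lncRNA spans and 4.19% of those outside genes. In pseudogene spans, which held 1.54% of all exons, they made up 7.57%, close to the protein-coding value. Of the 260125 exons seen in 1 library, 48.8% lay in protein-coding spans and 36.6% outside genes. Of the 11249 exons seen in 16 to 23 libraries, 78.2% lay in protein-coding spans and 14.6% outside genes. The protein-coding percentage was 15.97 ± 4.35 percentage points higher among exons found in at least 10 libraries than among exons found in 1 library (SD, n = 22; higher on 22 of 22 chromosomes; permutation p = 2e-05, adjusted p = 2e-05). Reads rose along with recurrence, from a median of 261 in exons of 1 library to 38986 in exons of 16 to 23 libraries, so number of libraries and read depth were not separated here.

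Coding exons that keep the reading frame when skipped have a length divisible by 3, and trapped exons in protein-coding spans had an excess of such lengths. The sources do not state how starts are counted, and this excess was 1 of the reasons for taking end minus start as length, so which remainder is in excess is not independent evidence. In protein-coding spans 34.6% of exons had such a length (95% Wilson interval 34.5 to 34.7%), compared with 33.5% outside genes (33.3 to 33.6%) and 33.5% in lncRNA spans (33.2 to 33.7%). Among exons of at least 10 libraries, the protein-coding share was 37.3% (36.9 to 37.7%) and the share outside genes was 33.3% (32.7 to 34.0%). Pseudogene spans also stood at 37.3% (35.0 to 39.6%, 1702 exons), and lncRNA spans at 33.6% (32.5 to 34.7%). Spans of other genes gave 41.5% (34.1 to 49.3%, 159 exons). The excess among these exons was therefore not particular to protein-coding spans. The share reached 39.1% (38.1 to 40.2%) in protein-coding exons of 16 to 23 libraries, while exons outside genes stood at 31.7% (29.5 to 34.0%). The other remainders of division by 3 made up 30.9% and 30.0% of these protein-coding exons, so the uneven shares themselves do not rest on how starts are counted. Libraries share exons to different degrees, so their number is not a count of independent recoveries. The difference between protein-coding spans and sequence outside genes was 1.15 ± 0.52 percentage points over all exons (higher on 22 of 22 chromosomes) and 4.14 ± 2.15 points among exons of at least 10 libraries (SD, n = 22; higher on 21 of 22 chromosomes; permutation p = 1e-05 and adjusted p = 1.29e-05 for both). The exception was chromosome 14, at -0.50 points. With only exons of at least 1000 reads, the first difference was 2.02 points. Intervals cover counting error only, and the comparison of lengths by 3 was chosen after the data were seen.

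**Figure D2:**
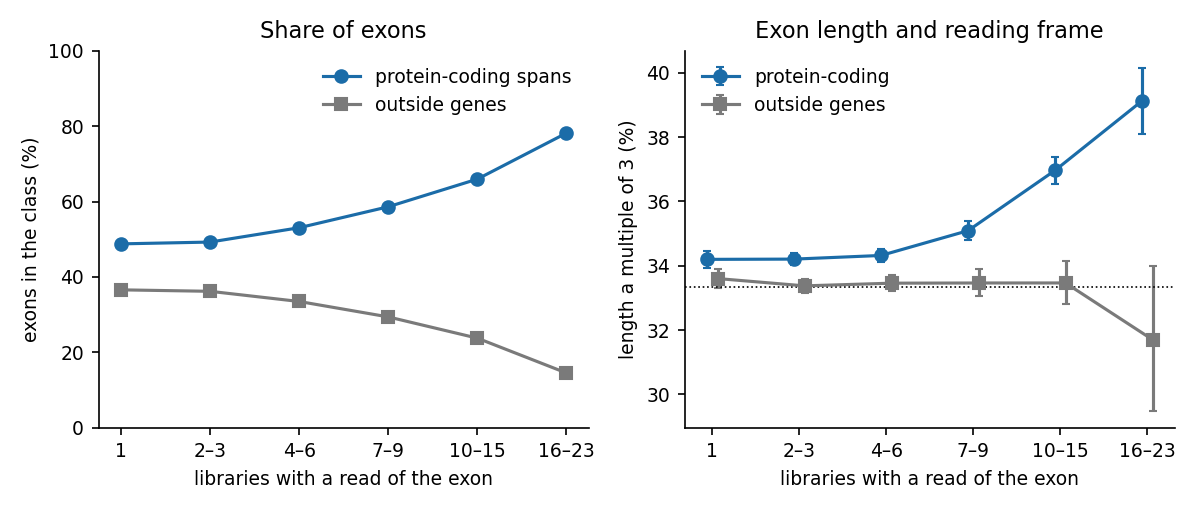
Left, share of exons (vertical axis, %) in protein-coding spans and outside genes by the number of libraries with a read of the exon (horizontal axis). Right, share of exons with a length divisible by 3 (vertical axis, %, axis not starting at 0) with 95% Wilson intervals, where protein-coding exons rise from 34.2% in 1 library to 39.1% in 16 to 23 libraries and the dotted line marks equal shares of the 3 remainders.

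Exon length varied with class. Protein-coding spans had longer exons, with a median of 143.0 ± 5.8 nt against 134.8 ± 4.7 nt outside genes (mean ± SD of chromosome medians, n = 22), a difference of 8.1 ± 3.0 nt found on 22 of 22 chromosomes (permutation p = 1e-05, adjusted p = 1.29e-05). Counting 1 exon per group of overlapping exons, an alternative added later, reduced it to 4.4 nt. Exons in pseudogene spans were longer still, with a median of 154.4 ± 6.2 nt. Exons over 100 and up to 200 nt made up 49.3% of the exons on analysed chromosomes, and exons over 50 and up to 100 nt made up 25.03%. Exons of 28 to 50 nt made up 1.03%, and 2 exons had 27 nt or less. Exons over 500 nt (0.92%) had a protein-coding share of 70.0%, and 0.22% of them were seen in at least 10 libraries. For exons over 100 and up to 200 nt these shares were 51.9% and 7.31%.

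Many trapped exons shared an end with another. The exons fell into 930543 groups of overlapping exons on the same strand. Among 1145708 distinct 5′ splice sites, which lie at the downstream end of an exon, 19.5% served more than 1 exon, and among 1239288 distinct 3′ splice sites, at the upstream end, 14.5% did. The difference was 5.11 ± 0.53 percentage points and had the same direction on 22 of 22 chromosomes (SD, n = 22; permutation p = 1e-05, adjusted p = 1.29e-05). With only exons of at least 1000 reads it was 2.41 points.

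The strongest of the exons seen in every library lay in genes of varied function. On the analysed chromosomes 157 exons had reads in all 23 libraries, of which 125 lay in protein-coding spans, 5 in lncRNA spans and 20 outside genes. The top exon, of 135 nt in KRTCAP3 (chromosome 2, 27443399 to 27443533, plus strand), had 253663 reads in total, with a median of 6693 and a range of 3 to 64634 reads per library. An exon of 165 nt in DNM2, which encodes the endocytic GTPase dynamin 2 (chromosome 19, 10825058 to 10825222), had 207726 reads, and an exon of 159 nt in the Polycomb gene PHC2 (chromosome 1, 33372290 to 33372448) had 204103. VPS26C (chromosome 21, 37227655 to 37227807) followed with 201975 reads, and CDC34, a ubiquitin-conjugating enzyme (chromosome 19, 536244 to 536341), with 192533. The remaining 5 of the 10 were in SEMA7A (174958 reads), ATP5F1D (171300), MYBBP1A (168614), MED24 (167109) and TRAF2 (162474). Reads of such an exon differed widely between libraries: the MYBBP1A exon had between 1 and 48497 reads per library, with a median of 16. Whether these positions match annotated exons was not analysed here.

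Exons in every library were also found far from protein-coding genes. The strongest outside annotated genes had 129 nt and 178277 reads, on the plus strand of chromosome X from 73861816 to 73861944, 174.7 kb from CHIC1, the nearest protein-coding gene. Others lay on chromosome 15 from 101561245 to 101561406 (125806 reads, 71.5 kb from PCSK6), on chromosome 16 from 38211 to 38311 (104884 reads, 8.1 kb from POLR3K) and on chromosome 10 from 71012895 to 71013030 (92363 reads, 124.3 kb from PCBD1). The fifth, on chromosome 21 from 43696336 to 43696421, had 61194 reads and lay 0.26 kb from RRP1B. Presence in every library rested on few reads for some. The chromosome 10 exon had a median of 7 reads per library (range 1 to 41156), and the chromosome 21 exon a median of 4 (range 1 to 29394). Medians for the exons on chromosomes X, 15 and 16 were 5461, 3016 and 4092.

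Nearly all genes yielded at least 1 exon. Of 18524 protein-coding genes, 17682 (95.5%) held a trapped exon and 12502 (67.5%) held an exon found in at least 10 libraries. The median protein-coding gene held 22 exons, or 8.15 per 10 kb of gene span, with quartiles of 4.12 and 14.96 per 10 kb. Of 17097 lncRNA genes, 15604 (91.3%) held a trapped exon, with a median of 7 exons, and 31.8% held an exon found in at least 10 libraries. These lncRNA counts include exons that also lie in overlapping protein-coding spans.

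Among genes with at least 20 exons, the densest were short, which the limit itself favours because a short gene reaches it only at high density. PSMB10, an immunoproteasome subunit, held 34 exons in 2.35 kb of chromosome 16, or 145.0 per 10 kb. ZFAND2B held 33 exons (115.1 per 10 kb), JMJD8 29 (108.8), ABHD11 27 (99.7) and PRPH, which encodes the neuronal intermediate filament peripherin, 35 (98.9). At the other end, ANXA8 held 32 exons over 523.8 kb (0.61 per 10 kb), PDE4DIP 22 (0.98), TEX9 24 (1.11), RFX3, a transcription factor of ciliated cells, 38 (1.23) and STPG2 87 (1.24). Near-identical copies of a gene can lose reads in mapping, and ANXA8 and PDE4DIP have such copies.

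Very large genes held the most exons, on both strands. PTPRN2, a receptor-type phosphatase gene of 1049 kb on chromosome 7, held 1684 exons, 955 on the plus strand and 729 on the minus strand. RBFOX1, which encodes a neuronal splicing factor, held 655 on the plus and 820 on the minus strand, and KAZN held 441 and 541. DLGAP2 (540 on the minus strand) and CDH4 (511 on the minus strand) were the others with most exons on their fuller strand. DAB1 (437 on the minus strand) and ASIC2 (431 on the minus strand) joined the first 3 genes in holding the most on their emptier strand.

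Gene lists fixed before the data were examined were compared with random lists of genes of like length, a test that replaced the planned one. With all exons and matching on length alone, collagens, the fibrous proteins of the extracellular matrix, were the list farthest above its matched lists. The list of muscle genes was farthest above with at least 1000 reads, with at least 5 or at least 10 libraries, and with 1 exon per overlapping group. The 21 collagen genes held 2573 exons, and their median density was 2.29-fold that of matched genes, a log2 difference of 1.20. Above the median of their own matched genes were 14 of 21 and below it 7, and no random list of 10000 reached the list's median (two-sided p = 0.0002, n = 21 genes, the smallest these lists can give, Benjamini-Hochberg adjusted p = 0.0024 over 12 lists). COL1A1, of fibrillar collagen I, held 112 exons in 17.5 kb (63.9 per 10 kb), and COL7A1, of anchoring fibrils, held 155 (49.6 per 10 kb). COL11A1 held 46 (1.98 per 10 kb) and COL5A2 94 (2.30 per 10 kb). Counting only exons found in at least 10 libraries, the collagen difference was 0.61 with an adjusted p of 0.34.

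Structural genes of skeletal and cardiac muscle held more trapped exons than matched genes by 0.94 on the log2 scale, or 1.92-fold, with 19 of 21 genes above their matched median (two-sided p = 0.0008, adjusted p = 0.004, n = 21 genes). MYH7, the slow myosin heavy chain, held 99 exons (43.2 per 10 kb). The lowest were DMD, with 576 exons over 2220 kb (2.59 per 10 kb), and MYBPC1, with 45 (4.46 per 10 kb). The call did not hold when matched genes were also alike in the exon density of the 1 Mb around them (difference 0.52, adjusted p = 0.053, n = 21 genes).

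Core spliceosome genes exceeded their matched genes by 0.86 on the log2 scale, or 1.82-fold, with 15 of 20 genes above (two-sided p = 0.001, adjusted p = 0.004, n = 20 genes). SNRNP200 and PRPF8, both components of the U5 particle, held 104 exons (33.3 per 10 kb) and 112 exons (32.7 per 10 kb). The lowest values were 26 exons (2.204 per 10 kb) in AQR and 23 (5.08 per 10 kb) in SF3B1, a component of the U2 particle. With matching on local exon density the difference was 0.45 and the call did not hold (adjusted p = 0.060, n = 20 genes). Housekeeping enzymes and cytoskeletal genes were higher by 0.83, or 1.78-fold, with 12 of 18 genes above (two-sided p = 0.0058, adjusted p = 0.014, n = 18 genes). ACTG1, a cytoplasmic actin, held 15 exons (53.0 per 10 kb) and ALDOA, a glycolytic aldolase, 31 (50.5 per 10 kb), whereas LDHB held 10 (4.44 per 10 kb) and HSPD1 9 (6.57 per 10 kb). This call did not hold when overlapping exons were counted once (adjusted p = 0.072), with exons of at least 5 or at least 10 libraries (adjusted p = 0.34 and 0.18), or when 1 of the 23 libraries was left out (adjusted p = 0.054, n = 18 genes).

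Long noncoding RNA genes on the fixed list held more exons than other lncRNA genes of like length, by 0.92 on the log2 scale or 1.89-fold, with 14 of 16 above (two-sided p = 0.0056, adjusted p = 0.014, n = 16 genes). HOTAIRM1 and HOTTIP, both transcribed from the HOXA cluster, held 9 exons (21.6 per 10 kb) and 12 exons (17.5 per 10 kb), while DLEU2 held 40 (2.80 per 10 kb) and CDKN2B-AS1 67 (5.02 per 10 kb). With exons of at least 5 libraries the difference was larger, at 1.14, but the adjusted p was 0.086. The 5 lists that passed the threshold had a positive difference under every alternative run, but each of them lost its call under at least 1 alternative.

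The other 7 lists did not pass. Genes of SR proteins and TRA2, splicing activators, had a log2 difference of -0.68 with 8 of 12 below their matched genes (adjusted p = 0.17, n = 12 genes). SRSF2 held 11 exons (33.4 per 10 kb) and SRSF7 15 (18.997), while TRA2A held 15 (5.51) and TRA2B 16 (6.82), 9 of them found in at least 10 libraries. Genes of hnRNP and PTB proteins had a difference of -0.08 in their median although 16 of 21 were below their own matched genes (adjusted p = 0.77, n = 21 genes). PTBP1, a repressor of neuronal exons, held 31 exons (20.9 per 10 kb) and HNRNPAB 10 (15.1), although HNRNPAB lay at percentile 44 of genes of like length. PTBP2, the neuronal paralog of PTBP1, held 23 (2.26) and HNRNPR 8 (2.02). Cytosolic ribosomal protein genes had a difference of -0.20 (adjusted p = 0.57, n = 23 genes), with 13 exons in RPL10A (54.6 per 10 kb) and 10 in RPL6 (7.32).

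Liver-restricted genes of plasma proteins and metabolism had a difference of -0.52, with 16 of 23 below their matched genes (adjusted p = 0.17, n = 23 genes). C3, the central complement protein, held 107 exons (24.9 per 10 kb) and SERPINA1 29 (20.9), while CPS1, a urea cycle enzyme, held 58 (2.88). Neuronal synaptic and channel genes had a difference of 0.22 (adjusted p = 0.46, n = 26 genes), with 65 exons in NLGN3 (21.3 per 10 kb), 57 in GRIN1 (19.3), 33 in SCN2A (2.16) and 308 in PTPRD (1.34). Very long genes had a difference of -0.34 (adjusted p = 0.17, n = 23 genes), from 727 exons in WWOX (6.53 per 10 kb) and 735 in CDH13 (6.26) to 306 in LRP1B (1.61) and again PTPRD. Counting only exons found in at least 10 libraries, the adjusted p was 0.024 for the liver list, at a difference of -1.16, 0.014 for the neuronal list, at 1.20, and 0.024 for the very long genes, at -0.83.

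Disease genes with well-known splicing defects had a difference of -0.20 (adjusted p = 0.53, n = 23 genes), and 21 of 23 held a trapped exon. TSC2, mutated in tuberous sclerosis, held 167 exons (40.2 per 10 kb), 43 of them found in at least 10 libraries, and COL7A1 was again high. CEP290 held 24 exons (2.58 per 10 kb), and DMD was again low. The genes without an exon were SMN1 and SMN2, the near-identical pair of the spinal muscular atrophy locus, named here after their values were seen. These lists compare trapped exons per length of gene, so a gene with many annotated exons in a short span can rank high, and annotated exon numbers were not used here. Neighbouring genes within a list were treated as independent, so the p-values of lists with such genes may be too small.

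**Figure D3:**
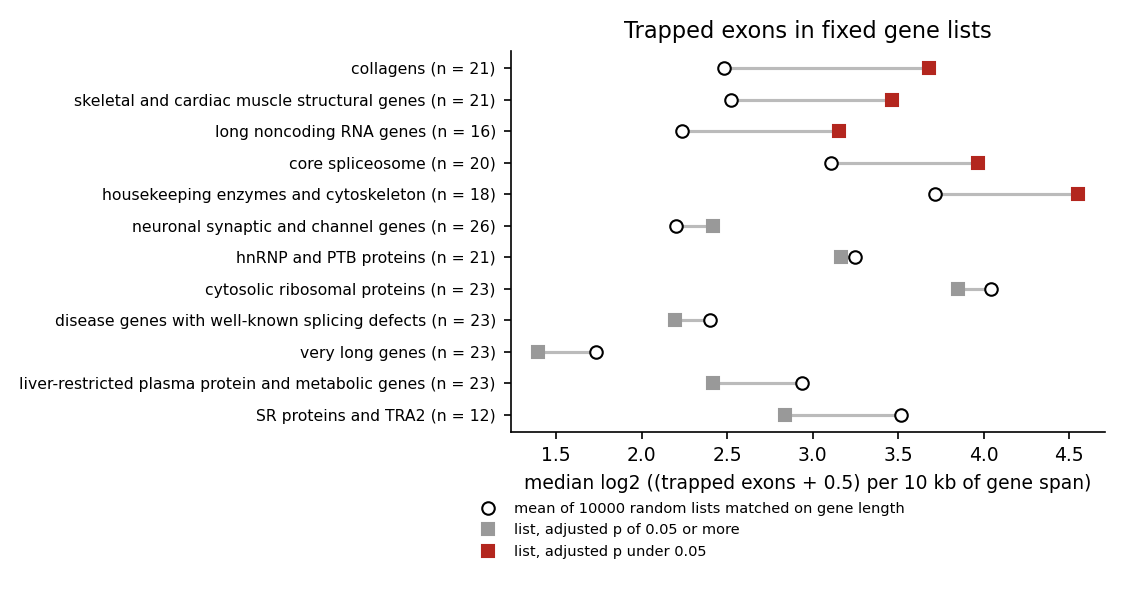
Median log2 of trapped exons plus 0.5 per 10 kb of gene span (horizontal axis) for the 12 fixed gene lists (rows, with the number of genes), as squares, beside the mean of 10000 random lists of genes of like length, as open circles. Red squares mark the 5 lists with an adjusted p under 0.05, all of which lie to the right of their circles.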

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

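Signals lay in 3 parts of the table that the comparisons did not use. The test on mitochondrial DNA was fixed before its value was seen.

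Mitochondrial DNA held 96 trapped exons, with 71 on the plus strand and 25 on the minus strand. Over 16.02 kb, the length up to the end of the last annotated mitochondrial gene, this was 11.2 times the density of the analysed chromosomes. Sequence beyond that gene was not counted in the length, so the ratio is somewhat too high. These exons were found in a median of 18.5 libraries (bootstrap 95% interval 14.5 to 21.5), against 3 for exons outside genes. Their median of 550 reads was close to the 511 of exons outside genes, while exons outside genes that reached 16 to 23 libraries had a median of 28495 reads. A candidate explanation is that many copies of mitochondrial DNA entered the fragment pools, which needs such exons in more libraries. The difference of 15.5 libraries goes with it. Other causes, such as carry-over of mitochondrial RNA, stay open, and no biological explanation was tested.

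Chromosome 11 held 7175 exons, each with reads in 1 library, the same for all of them, whereas the chromosomes of similar size next to it each held about 10 times as many. The remainder of chromosome 11 was not analysed here.

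Positions on chromosome Y were given to 95 exons, with 132248 reads and a median of 5 libraries. Whether these reads came from chromosome Y was not tested.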

How the results depend on the processing

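No paired analysis was possible because no library in the table carries an assay or a replicate letter. For the same reason alternatives on normalization, tool, replicate block, assays found, depth per assay and left-out replicates or assays were not run. The 0.5 added to the exon count of each gene was not varied, which would need no library names. Alternatives on exon matching, transcript tags, introns and repeats were not run because annotated exons and a genome were not used. Filters of 10 or 100 reads remove no exon of this table. Except for autosomes only and protein-coding genes only, all alternatives were chosen after the data were seen. The 9 genome-wide comparisons kept direction and threshold in all 45 alternatives and in 207 runs that each left out 1 library. The log2 density of genes over sequence outside genes ranged from 0.38 (1 exon per overlapping group) to 0.73 (at least 5 libraries). Shared splice sites could not be compared with 1 exon per group, nor exons of 1 library or of at least 10 libraries with a limit of 5 libraries. Gene lists depended more on the setting: of 72 list results, 55 kept direction and threshold. With exons in at least 10 libraries, collagens (0.61) and housekeeping genes (0.73) fell below the threshold, the liver (-1.16), neuronal (1.20) and very long (-0.83) lists passed it, making 2 lower lists, and the SR (0.74) and ribosomal protein (0.83) lists changed sign without passing. Exons in at least 5 libraries left 3 higher lists, as the housekeeping (0.51) and lncRNA (1.14) lists fell below the threshold, and the hnRNP (0.026) and ribosomal (0.11) lists changed sign. Matching on local exon density also left 3 higher lists, as the core spliceosome (0.45) and muscle (0.52) lists fell below the threshold, which they had passed before this matching was corrected for genes over 1 Mb, and the hnRNP list (0.053) changed sign. At 1000 reads the ribosomal (0.083) and disease gene (0.12) lists changed sign. The housekeeping list was 0.42 with 1 exon per group, below the threshold, and over runs without 1 library it ranged from 0.69 to 0.88 and lost its call in 1 run. Over these runs the hnRNP list ranged from -0.36 to -0.033 and the ribosomal list from -0.36 to -0.15, without passing the threshold. The causes were not tested. Fewer exons enter each gene under the stricter limits, which widens the error of a list.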

Other observations

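The tests on genes without exons, on chance in the strand comparison and on single families with few introns, and all gene families, were chosen only after the results had been seen. The strand tests on other genes inside the span, on repeated counting and on 30 other genes were fixed before their values were seen. How the test on 30 other genes is read was changed after its values were seen.

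Some gene families differed in trapped exons from protein-coding genes of like length. Of 22 families, 10 were higher and 3 lower (two-sided random list test, adjusted p under 0.05). These include core histones, beta-defensins and olfactory receptors. Members of those families hold so few exons that the 0.5 added to each count shapes the result. Myosin heavy chains, the motors of muscle and other cells, were 1.97-fold denser with 15 of 15 genes above (adjusted p = 0.0031, n = 15). This family shares members such as MYH7 with the fixed muscle list, which lost its call with matching on local exon density, so it is not a separate result. Integrins, which anchor cells to matrix, were 1.90-fold denser with 21 of 27 above (adjusted p = 0.00073, n = 27), laminins 1.90-fold with 11 of 12 above (adjusted p = 0.018, n = 12), adhesion G protein-coupled receptors 1.68-fold with 20 of 28 above (adjusted p = 0.0048) and ABC transporters 1.57-fold with 30 of 43 above (adjusted p = 0.0044). Keratins (1.44-fold), potassium channels (1.41-fold) and solute carriers (1.24-fold) were higher too. Clustered protocadherins (1.58-fold) also passed, but the spans of many of them are nested, so the same exons were counted for several members, which are not independent genes. Neighbouring genes of the other families were treated as independent as well. Of 37 beta-defensin genes, 34 were below and 18 held no exon (adjusted p = 0.00073, n = 37). With so few exons, the 0.5 added to each count sets the size of that difference. Zinc finger (ZNF) genes, with a median of 16 exons, were 1.34-fold sparser, with 351 of 503 below (adjusted p = 0.00073, n = 503). The families were not recomputed under alternatives.

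Families whose coding sequence lies mostly in 1 exon might hold few trapped exons, because an internal exon needs a splice site at each end. Olfactory receptors were 2.67-fold sparser with 169 of 219 below (percentile 0, adjusted p = 0.00073, n = 219). They held a median of 2 exons and 58 of them held none, so the added 0.5 exons also shapes the size of this difference. Bitter taste receptors, with a median of 0.5 exons, lay at percentile 7.87 (adjusted p = 0.25, n = 24). Core histones, with a median span of 0.49 kb and a median of 1 exon, lay at percentile 100, although 24 of 65 held no exon. For taste receptors and histones the added 0.5 exons largely sets the density, so neither percentile decides whether few introns matter there.

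In very long genes more trapped exons lay antisense than sense. Strands of 23 genes of the fixed list were taken from general knowledge, since the gene table used has none. Antisense exons made up 56.7 ± 3.0% (mean ± SD, n = 23 genes), above 50% in 23 of 23 genes, from 50.5% in CTNNA3 to 62.2% in CNTNAP2, and chance is argued against by the sign-flip permutation p of 1e-05, the smallest possible. The excess was 56.9% outside other gene spans and 55.7% with 1 exon per overlapping group (permutation p = 1e-05 for each), which argues against other genes inside the span and against repeated counting of a locus. A test on 30 other long genes of the fixed lists did not decide whether the excess extends beyond the chosen 23 genes. For exons in at most 4 libraries, 51.6 ± 11.2% were antisense (mean ± SD over genes, 22 of 30 genes above 50%, 52.7% of the pooled exons, permutation p = 0.44), from 22.9% in COL11A1 to 63.9% in COL14A1, and all exons gave 49.9% (permutation p = 0.96). In the 23 genes, exons of at least 10 libraries gave 59.1 ± 25.9% (permutation p = 0.11). The first attempt, made before these, took a gene's strand from its own exons in at least 10 libraries. It gave 49.4% of the exons in at most 4 libraries on the other strand in 45 genes over 500 kb and 34.3% in genes under 50 kb. Only 1 of the 23 genes could be given a strand in this way, and it was given the antisense strand, so this attempt does not bear on the question. Whether the excess is a property of the chosen 23 genes stays open, because the other genes went both ways.

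Of 18524 protein-coding genes, 842 (4.55%) held no trapped exon. Short gene length may account for many, as their median span was 2.0 kb against 25.4 kb for protein-coding genes as a whole, but 26 of the 7038 genes over 40 kb were empty too. A candidate explanation for these is that reads that map to 2 places were left out. It needs few exons in genes at the ends of X that are shared with Y, and these 18 genes held 0 exons, 0% of the 624.8 expected from other X genes of like length. Among the 26 are 8 of these genes, including DHRSX (281.5 kb) and CD99, and members of duplicated families such as SMN1 and SMN2, RGPD1 and RGPD6, and NOTCH2NLA. A biological explanation was not tested.

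Divided by the exons they shared into 5 sets, a number fixed in advance as that of the assays, the 23 libraries gave sets of 5, 4, 5, 4 and 5 libraries. Correlations of exon presence, from which the sets were built, were 0.12 to 0.39 within sets and 0.03 to 0.13 between them, so the ranges overlapped. Exons per library on the analysed chromosomes were 287448, 295708, 318083, 344382 and 347539 in the first set and 203905, 235481, 247463 and 257404 in the second. The third had 168373, 178287, 180557, 190806 and 200196, the fourth 170649, 184689, 194789 and 244732, and the fifth 278820, 343403, 353672, 388202 and 409849. The sets were found from the data and were not tied to assays or used in any comparison. Exons found in all 5 sets were 73112, or 5.00% of the exons on analysed chromosomes, and 29.1% were found in 1 set. Of the exons found in all 5 sets, 35.6% in protein-coding spans and 33.6% outside genes had a length divisible by 3. The gap was smaller than among exons of 16 to 23 libraries, but exons in all 5 sets can have as few as 5 libraries. For exons of at least 5 libraries, the mean difference over chromosomes was 1.95 percentage points.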
